A study of Mus musculus with 12 samples.

How the data were processed

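The libraries were made from DC2.4 cells, a mouse dendritic cell line. Per the labels' protocols, cells were seeded in 12-well plates and treated with PBS, ATEV at 15 µg/mL, NTEV at 30 µg/mL or DNase-pretreated ATEV at 15 µg/mL; a day later each group was collected and plated again, with 3 repeats of these steps, whether as rounds on the same cells or as separate experiments is unclear. RNA was purified with a column kit and libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, TopHat2 2.0.11, TopHat, Cufflinks 2.1.1 and the mouse build mm9. The read counter, the gene annotation and the strand setting used for counting were not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart with certainty. The values analysed are whole-number counts per gene as deposited, 1 column per library, with no normalization by the authors visible in the values.

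The table lists 42687 Ensembl gene identifiers, of which 42250 were matched to gene symbols of GENCODE M21; 437 were not. No coordinates are printed, because that annotation belongs to another build than the submitters named. No column was left unassigned to a sample. Each library was assigned to its group from the treatment label and to its replicate number from its title. Library totals ran from 19.4 to 30.4 M counts. A gene's count sets its counting error, and intervals and floors given for genes with few counts cover counting error only. The most abundant gene took 1.11 to 2.05% of a library. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 14.7 to 130, so no library was counted as a copy of another.

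Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 13261. Library sizes were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries, which share 1 estimate of the spread (common biological coefficient of variation 0.183), and 5 contrasts were tested: ATEV, DNase-treated ATEV and NTEV each against PBS, and ATEV against DNase-treated ATEV and against NTEV. All adjusted p-values of genes come from this edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment over the 13261 genes within a contrast, unless another tool is named, and a gene is called at an adjusted p under 0.05. The tests are two-sided. Log2 fold changes are edgeR's, with standard errors derived from the F statistic. Levels are TMM-scaled CPM (counts per 1e6 normalised counts) given as mean ± SD over 3 libraries. A fold against a group with 0 counts is a lower bound that sets the group at 3 counts over its libraries. With 1 to 3 counts a ratio is given with its exact 95% counting interval.

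The gene lists, the comparisons, the tests, the rule for named genes and the alternatives were fixed before the data were examined. There are 21 gene lists: type I interferon-stimulated genes, cytosolic and endosomal DNA sensing, MHC class I and MHC class II antigen processing and presentation, dendritic cell maturation and costimulation, NF-kB targets and inflammatory cytokines, interferon-gamma-inducible GTPases and effectors, lysosome and phagosome, cell cycle and DNA replication, p53 targets, unfolded protein and integrated stress response, cholesterol biosynthesis and uptake, glycolysis and hypoxia, oxidative stress response, immediate early genes, mitochondrially encoded mRNAs, and markers of T cells, B cells, macrophages, dendritic cell lineages and fibroblasts. A list was tested when at least 5 of its members were tested, which held for 19. The list test was limma's camera with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 19 lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, were alternatives. With an estimated correlation 5 of the 11 lists called for ATEV against PBS held, 0 of 9 for DNase-treated ATEV against PBS, 1 of 8 for NTEV against PBS, 5 of 13 for ATEV against DNase-treated ATEV and 3 of 7 for ATEV against NTEV.

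Named genes were drawn, for each contrast, from the 8 largest rises and 8 largest falls among called genes with at least 1 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes and clone names; from up to 4 called members of each list with the smallest adjusted p; and from a fixed panel of interferon, antigen presentation, costimulation and DNA sensing genes. Genes named outside that rule are said to be so. Some genes that meet the rule are not reported here. The mitochondrially encoded list had no member in the table used and was not analysed here.

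The scripts were tested on simulated counts drawn with the real means, library sizes and dispersions. For the gene test the changed genes were picked among those with a mean of at least 1 CPM. Recovery of genes below that level was not measured. Of 100 genes changed 2-fold, 64% were recovered for ATEV against PBS, 73% for DNase-treated ATEV against PBS, 74% for NTEV against PBS, 73% for ATEV against DNase-treated ATEV and 78% for ATEV against NTEV, and of 100 genes changed 4-fold 97%, 99%, 97%, 96% and 96% were. False calls made up 1.23 to 6.45% of calls over the 5 simulations. In 20 simulations of ATEV against PBS, a list of 20 genes changed 1.5-fold was called by camera in 20 and an unchanged list in 0. Simulated genes varied independently, whereas the estimated inter-gene correlation of the real cell cycle list was 0.666 in this contrast. The 0 is therefore no measure of false calls for lists of correlated genes.

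Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 5 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, a test against a minimum fold of 1.5, and each library of the compared groups left out in turn. Correlations and covariances of fold changes of comparisons that share the PBS libraries were set beside 20 simulations of unchanged groups against shared controls.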

Results

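Gene expression was measured by stranded mRNA sequencing in DC2.4 cells, an immortalised mouse dendritic cell line, after exposure to extracellular vesicles shed by T cells. The 12 libraries formed 4 groups of 3. Control cells received phosphate-buffered saline (PBS). A further group received 15 µg/mL of vesicles from activated T cells (ATEV), and another received 30 µg/mL of vesicles from non-activated T cells (NTEV). The last group received 15 µg/mL of ATEV that had been pretreated with Baseline-ZERO DNase, a DNA-degrading enzyme (DNase-treated ATEV). A note in the labels, 5 µg/mL of vesicle DNA, follows the NTEV dose and may cover the ATEV dose too; the vesicle amount itself differed between these groups. The labels give 3 repeats of the procedure, which may mean 3 rounds of treatment of the same cells or 3 separate experiments. Libraries held 19.4 to 30.4 M gene counts (1 M = 1e6), with means of 23.8 ± 2.36 M for PBS, 20.8 ± 1.41 M for ATEV, 24.9 ± 5.05 M for NTEV and 21.4 ± 1.46 M for DNase-treated ATEV (SD, n = 3). Of 42687 gene identifiers, 13261 carried enough counts to be tested. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

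Along the first principal component, which held 34.9% of the variance, the PBS libraries lay at -41.8, -28.4 and -14.6 and the ATEV libraries at 31.1, 25.3 and 9.33. Libraries of the remaining groups were spread more widely. NTEV replicate 1 (-21.5) and DNase-treated ATEV replicate 1 (-30.4) lay among the PBS libraries, whereas the other NTEV libraries lay at 41.7 and 15.0 and the other DNase-treated libraries at 4.41 and 9.81. ATEV replicates 2 and 3 also stood apart on the second component, at 27.9 and 48.3, against -2.03 for ATEV replicate 1.

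**Figure D1:**
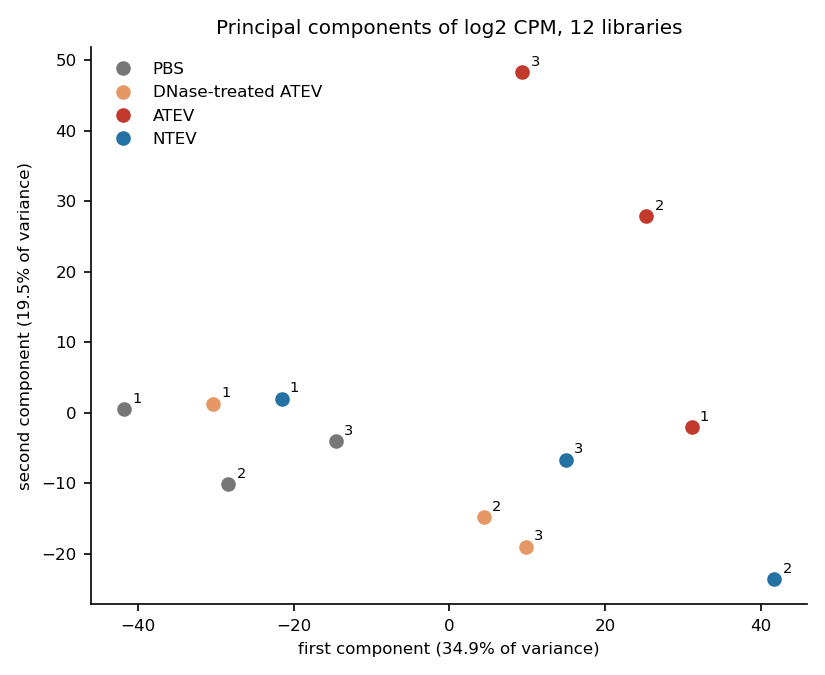
Principal components of log2 CPM over all tested genes, with the first component (34.9% of variance) on the x axis and the second (19.5%) on the y axis; each point is 1 library, coloured by group and numbered by replicate. PBS libraries lie on the left, between -41.8 and -14.6, and ATEV libraries on the right, between 9.33 and 31.1, while NTEV and DNase-treated ATEV libraries span both sides.

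The comparison of ATEV with PBS asks how DC2.4 cells responded to vesicles of activated T cells. ATEV-treated cells held much more mRNA of interferon-inducible genes. Gbp2, a guanylate-binding GTPase of cell-autonomous immunity, stood at 39.6 ± 8.02 CPM (counts per 1e6 normalised counts) against 0.805 ± 0.307 in PBS (SD, n = 3), a log2 fold change of 5.59 ± 0.39 (SE, adjusted p = 3.82e-06). Its relatives Gbp3 and Gbp7 rose by 3.56 and 3.91 on the log2 scale, and the immunity-related GTPase Irgm2 by 3.19. Iigp1, another GTPase of this class, had no counts in PBS and 13.3 ± 2.92 CPM with ATEV, which made it at least 304-fold higher against a floor of 3 counts over the PBS group. On the same floor, Tgtp2 was at least 367-fold and the serine protease inhibitor Serpina3f at least 111-fold higher. Gbp5 had 126 counts with ATEV and 2 with PBS, a ratio of 69.5 with a 95% counting interval of 18.8 to 580.2, and Gbp6 had 82 against 3, a ratio of 30.2 (9.96 to 149). The list of interferon-gamma-inducible GTPases and effectors had 18 tested members, of which 17 rose and none fell (17 adjusted over the list alone; median log2 fold change 2.58; camera adjusted p = 9.88e-67, and adjusted p = 2.16e-05 with an estimated correlation). Iigp1 placed at its bound stays above that median and leaves it as it is. Of the 17 calls, 13 were kept in each of the 6 fits that left out 1 library. Several of these genes (Iigp1, Tgtp2, the Gbp cluster and Serpina3f) have close copies in the mouse genome, so the share of reads assigned to each copy is uncertain.

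Type I interferon-stimulated genes, an overlapping programme, rose as well, with 30 of 43 tested members higher and none lower (35 adjusted over the list alone; median 1.40; camera adjusted p = 5.44e-41, and adjusted p = 0.0011 with an estimated correlation). Lgals3bp, a secreted galectin-binding glycoprotein, had the smallest adjusted p of all genes tested here (8.52e-07) and rose from 17.7 ± 0.731 to 80.3 ± 5.71 CPM. Zbp1, a sensor of Z-form nucleic acids, rose by 5.43 on the log2 scale, Irf7 by 2.08, the ubiquitin-like modifier Isg15 by 2.04 and the ADP-ribosyltransferase Parp14 by 1.86. The surface antigen Ly6a, another gene known to be inducible by interferon, rose by 5.05. Ifit1 (0.51 ± 0.50, adjusted p = 0.529) and the chemokine Cxcl10 (0.63 ± 0.51, adjusted p = 0.437) did not pass the test at levels below 1 CPM. Transcripts of Ifnb1, Il12b and Trex1 had 0 counts in all 12 libraries. The read counter was not given and may drop reads of overlapping genes, so 0 counts need not mean an absent transcript. The 30 calls of this list included 16 that were kept in all 6 fits with 1 library left out.

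**Figure D2:**
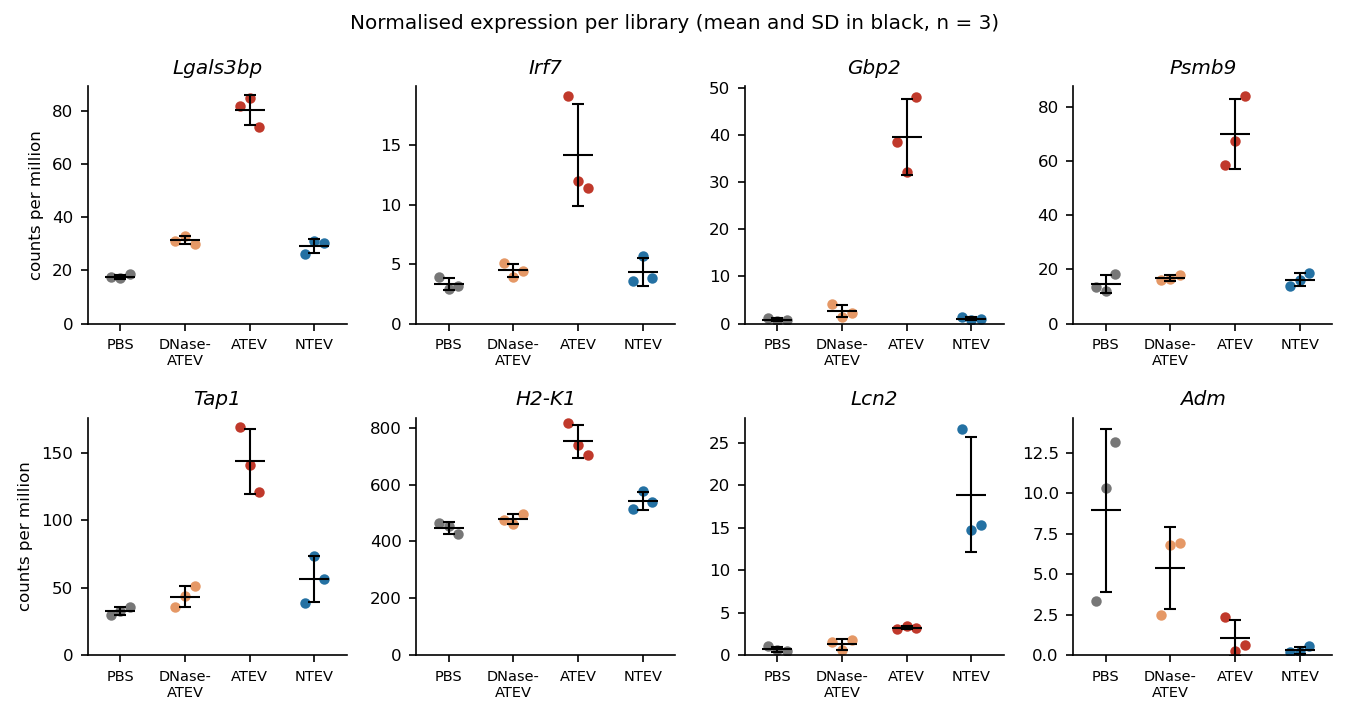
Normalised expression in CPM (y axis, starting at 0) of 8 genes in the 4 groups (x axis); each point is 1 library, and black bars give the mean and SD (n = 3). Lgals3bp, Irf7, Gbp2, Psmb9, Tap1 and H2-K1 were highest with ATEV, Lcn2 was highest with NTEV at 18.9 CPM, and Adm was lowest with ATEV and NTEV.

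Antigen presentation through MHC class I moved with the interferon genes. In that list, 19 of 23 tested members rose and none fell (20 higher and 1 lower adjusted over the list alone; median 1.07; camera adjusted p = 3.43e-36, and adjusted p = 2.16e-05 with an estimated correlation). Psmb9, an immunoproteasome subunit, increased from 14.6 ± 3.36 to 70.0 ± 13 CPM (log2 fold change 2.26 ± 0.19, adjusted p = 2.18e-05). Tap1, which carries peptides into the endoplasmic reticulum, rose from 32.8 ± 3.21 to 144 ± 24.3 CPM. The peptide editor Tapbpl rose by 1.75 on the log2 scale, the class I transactivator Nlrc5 by 1.07, the immunoproteasome subunit Psmb8 by 1.07, and the class I heavy chains H2-Q4, H2-D1 and H2-K1 by 2.28, 0.96 and 0.75. B2m, the light chain of class I molecules, rose by 0.76, a call that was lost without PBS replicate 1 or PBS replicate 2 (adjusted p up to 0.0645). In all, 15 of the 19 calls were kept whichever library was left out. H2 heavy-chain genes are near-identical in places, so their individual values are uncertain.

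Of the 18 listed MHC class II genes 11 had enough counts to be tested, and 3 of these rose (3 adjusted over the list alone; median 0.41; camera adjusted p = 0.0499, and adjusted p = 0.245 with an estimated correlation). This list lost its call without PBS replicate 1 (adjusted p = 0.0572). Ctss, the protease that trims the invariant chain, rose by 0.80, while the invariant chain Cd74 itself did not pass (0.44 ± 0.22, adjusted p = 0.216). Dendritic cell maturation and costimulation genes had 5 of 14 tested members higher and none lower (11 higher adjusted over the list alone; median 0.86; camera adjusted p = 2.44e-06, and adjusted p = 0.0389 with an estimated correlation). Cd40, the receptor through which T cells license dendritic cells, increased from 8.95 ± 2.34 to 26.2 ± 5.36 CPM (log2 fold change 1.55 ± 0.26, adjusted p = 0.00546), and Il15ra, which presents interleukin-15, rose by 0.97. The costimulatory ligand Cd80 rose by 0.96, but its call was lost with any 1 of the 6 libraries left out (adjusted p up to 0.118). Cd86 did not pass (0.41 ± 0.17, adjusted p = 0.155).

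Among NF-kB targets and inflammatory cytokines, 7 of 26 tested members rose and none fell (11 higher adjusted over the list alone; median 0.54; camera adjusted p = 8.35e-07, and adjusted p = 0.00249 with an estimated correlation). The chemokine Cxcl16 rose by 2.04 and the cytokine subunit Il27 by 2.71, and both calls were kept whichever library was left out. Lcn2, an iron-sequestering protein of acute inflammation, rose by 2.18, a call lost without PBS replicate 2 (adjusted p = 0.0640). Tnf was not called (0.82 ± 0.28, adjusted p = 0.0992), although without PBS replicate 3 it was (adjusted p = 0.00926). The list of cytosolic and endosomal DNA sensing genes was not called (camera adjusted p = 0.297), with 4 of 27 tested members higher and 1 lower (5 higher and 2 lower adjusted over the list alone); its median was -0.05 while its mean was 0.29. Its higher members were Zbp1, Ifi204, Ikbke and Pycard. Ifi204, a DNA-binding protein of the interferon-inducible p200 family, rose by 2.11. Ikbke lost its call without PBS replicate 2 (adjusted p = 0.0530), and Pycard without PBS replicate 1 or 2 or ATEV replicate 2 or 3 (adjusted p up to 0.0943). The DNA sensor Cgas (-0.18 ± 0.16, adjusted p = 0.478) and its adaptor Tmem173, also called STING (-0.15 ± 0.13, adjusted p = 0.480), did not pass.

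Fewer genes were lower with ATEV. Cd24a, a glycosylphosphatidylinositol-anchored surface protein, dropped from 65.4 ± 16.8 to 9.72 ± 1.61 CPM (log2 fold change -2.75 ± 0.28, adjusted p = 1.21e-04). The copper transporter Atp7b fell by 3.36 on the log2 scale. The transcription factor Maf fell by 2.11, a call lost without ATEV replicate 2 (adjusted p = 0.0736). F13a1, a clotting factor subunit also made by macrophages, fell by 2.33 and lost its call without PBS replicate 3, ATEV replicate 2 or ATEV replicate 3 (adjusted p up to 0.0836). After DNase-treated ATEV, Maf (-2.44, adjusted p = 0.0994) and F13a1 (-1.97, adjusted p = 0.413) lay below PBS too, without passing. Glycolysis and hypoxia genes were lower as a list, with 6 of 29 tested members down and none up (21 lower adjusted over the list alone; median -0.69; camera adjusted p = 1.44e-11, but adjusted p = 0.166 with an estimated correlation). Egln1, the oxygen-sensing prolyl hydroxylase, fell by 1.16 and was the sole member called in all 6 fits with 1 library left out. Hk2, the hexokinase that opens glycolysis, fell by 0.80, and its call was lost without PBS replicate 2 (adjusted p = 0.0560). Cell cycle and DNA replication genes had a median of -0.42, with 1 of 35 tested members lower (9 lower adjusted over the list alone; camera adjusted p = 1.13e-08, but adjusted p = 0.367 with an estimated correlation). That member, the spindle checkpoint kinase Bub1b, lost its call with any 1 of the 6 libraries left out (adjusted p up to 0.123).

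The other lists had small or mixed changes in this comparison. Macrophage markers had 3 members up and 1 down of 14 (5 up and 1 down adjusted over the list alone; median 0.48; camera adjusted p = 0.00613, but adjusted p = 0.304 with an estimated correlation), and the call was lost without PBS replicate 2 (adjusted p = 0.0504). Lyz2, the myeloid lysozyme, rose by 1.22 and lost its call without PBS replicate 2 (adjusted p = 0.0737). Lysosome and phagosome genes had 4 of 33 members up (7 adjusted over the list alone; median 0.22; camera adjusted p = 0.00292, but adjusted p = 0.245 with an estimated correlation), among them the protease Ctsh, which rose by 1.83. p53 targets had 3 of 23 members up (4 adjusted over the list alone; median 0.28; camera adjusted p = 0.0171, but adjusted p = 0.367 with an estimated correlation), and the list lost its call without ATEV replicate 1 (adjusted p = 0.105). Of these, the death receptor Fas rose by 2.18. Lists not called by camera were the unfolded protein and integrated stress response (0 of 26 members called, adjusted p = 0.174), cholesterol biosynthesis and uptake (0 of 24, 0.297), oxidative stress response (1 of 23, 0.609), immediate early genes (0 of 26, 0.745), dendritic cell lineage markers (3 up and 1 down of 12, 0.574), T cell markers (1 up and 1 down of 6, 0.272) and fibroblast and stromal markers (0 of 8, 0.609). Only 1 of 14 B cell markers could be tested, and mitochondrially encoded mRNAs were not analysed here.

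Over all genes, edgeR's quasi-likelihood test called 628 genes between ATEV and PBS at an adjusted p under 0.05, with 440 higher and 188 lower; DESeq2 called 848 higher and 668 lower. At least a 2-fold difference was fitted for 243 of the higher and 38 of the lower genes. Leaving out 1 library gave 235 (PBS replicate 1), 169 (PBS replicate 2), 315 (PBS replicate 3), 849 (ATEV replicate 1), 207 (ATEV replicate 2) and 284 (ATEV replicate 3) calls, and 149 genes (137 higher, 12 lower) were called in all 6 of these fits.

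The comparison of DNase-treated ATEV with PBS asks what response remained once the vesicles had been exposed to DNase. No gene passed the edgeR test between these groups. At an unadjusted p under 0.05 there were 791 genes, or 5.96% of those tested, and the smallest adjusted p was 0.0612. limma-voom also called 0 genes and DESeq2 called 37. Antigen presentation genes of the fixed panel included Tap1 at 43.4 ± 7.87 CPM against 32.8 ± 3.21 (SD, n = 3; log2 fold change 0.40 ± 0.21, adjusted p = 0.826), Psmb9 at 16.8 ± 1.02 against 14.6 ± 3.36 (0.20 ± 0.18, adjusted p = 0.837), H2-K1 at 478 ± 18.3 against 448 ± 20.6 (0.09 ± 0.11, adjusted p = 0.864) and Cd74 at 156 ± 35.3 against 97.2 ± 19.8 (0.68 ± 0.22, adjusted p = 0.708). Irf7 had a fold change of 0.42 ± 0.26, Isg15 of 0.36 ± 0.31 and Cd40 of -0.03 ± 0.26. The count of calls was 8 without DNase-treated ATEV replicate 1 and 2 without PBS replicate 1, and 0 without any other library.

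As lists, the interferon and class I genes were shifted upward relative to other genes in the camera test with the preset correlation. With an estimated correlation these 3 calls were lost, at adjusted p = 0.0723 for interferon-gamma-inducible, 0.375 for type I interferon-stimulated and 0.0723 for MHC class I genes. Fry, which does not compare a list with other genes, called the interferon-gamma-inducible and MHC class I lists higher (adjusted p = 0.0278 each). It did not call the type I interferon-stimulated list (adjusted p = 0.209). Medians were 0.29 for interferon-gamma-inducible genes (mean 0.60; camera adjusted p = 5.71e-06, 5 of 18 higher adjusted over the list alone), 0.25 for type I interferon-stimulated genes (5.52e-05, 2 of 43) and 0.17 for MHC class I genes (3.94e-04, 1 of 23). Without DNase-treated ATEV replicate 1 the call was lost for the type I interferon-stimulated list (adjusted p = 0.244) and the MHC class I list (adjusted p = 0.129). Of genes chosen after their values were seen, Gbp3 stood at 9.81 ± 1.57 CPM against 3.35 ± 0.972 (1.54 ± 0.22, adjusted p = 0.0612; called without PBS replicate 1, adjusted p = 0.0458), Gbp2 at 2.62 ± 1.31 against 0.805 ± 0.307 (1.68 ± 0.39, adjusted p = 0.400) and Gbp7 at 3.76 ± 0.369 against 1.78 ± 0.234 (1.08 ± 0.25, adjusted p = 0.399). MHC class II genes had a median of 0.23 (adjusted p = 0.0348, but adjusted p = 0.375 with an estimated correlation), a call lost without PBS replicate 1 (adjusted p = 0.201) or DNase-treated ATEV replicate 3 (adjusted p = 0.0650). Lower medians were found for cholesterol biosynthesis (-0.31), glycolysis and hypoxia (-0.26), oxidative stress (-0.23), cell cycle (-0.23) and fibroblast markers (-0.52), each with an adjusted p of 0.539 with an estimated correlation. Their camera adjusted p values were 9.25e-06, 6.47e-06, 3.08e-05, 5.71e-06 and 0.0381. The fibroblast list lost its call without PBS replicate 1 (adjusted p = 0.593) or DNase-treated ATEV replicate 1 (adjusted p = 0.468). Its tested members lay near the floor, with a median of 0.628 CPM in PBS. The remaining 10 of the 19 testable lists were not called.

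The comparison of NTEV with PBS asks how the cells responded to vesicles of T cells that had not been activated. Inflammatory genes were higher as a list, while no joint rise of interferon-inducible genes was called. Lcn2 rose from 0.692 ± 0.304 to 18.9 ± 6.74 CPM (SD, n = 3; log2 fold change 4.75 ± 0.41, adjusted p = 3.14e-04), and Fas rose from 2.56 ± 0.880 to 11.3 ± 3.8 CPM. Drops kept whichever library was left out included Adm, which encodes the vasoactive peptide adrenomedullin (8.94 ± 5.04 to 0.305 ± 0.211 CPM; -4.92 ± 0.80, adjusted p = 0.0116), F13a1 (115 ± 50.6 to 4.74 ± 2.16 CPM), Atp7b (-3.57), Maf (-3.43) and Cd24a (-2.42). Samd9l, an interferon-inducible antiviral gene, fell by 1.40. These 8 genes were called whichever library was left out. Adm, F13a1, Atp7b, Maf and Cd24a were among the genes with the lowest loadings on the first principal component. NTEV libraries spread from -21.5 to 41.7 along that component, so a culture state that differs between libraries was not excluded for these drops.

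NF-kB targets and inflammatory cytokines were the only list still called with an estimated correlation after NTEV, although 1 of its 9 called members was kept in all 6 fits with 1 library left out. Higher levels were found for 9 of 26 tested members and lower levels for none (11 higher adjusted over the list alone; median 0.63; camera adjusted p = 1.04e-12, and adjusted p = 6.29e-04 with an estimated correlation). Beside Lcn2, the chemokine Ccl5 rose by 2.89 and the acute-phase protein Saa3 by 2.66. Ccl5 lost its call without PBS replicate 2 or 3 (adjusted p up to 0.0689) and Saa3 without PBS replicate 2 or 3 or NTEV replicate 2 (adjusted p up to 0.0932). Nfkbia, the inhibitor that NF-kB induces, rose by 0.68, a call kept only without NTEV replicate 1 (adjusted p up to 0.114 without each of the other 5 libraries). Ly75, an endocytic receptor of dendritic cells, rose by 2.71, with its call lost without PBS replicate 2, PBS replicate 3 or NTEV replicate 3 (adjusted p up to 0.0623).

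Interferon-inducible genes showed no joint rise after NTEV. In the interferon-gamma-inducible list 1 member was higher and 1 lower of 18 (1 and 1 adjusted over the list alone; median -0.01, camera adjusted p = 0.780), and in the type I interferon-stimulated list 2 were higher and 2 lower of 43 (3 and 3 adjusted over the list alone; median 0.06, camera adjusted p = 0.764). Irf7 (0.38 ± 0.26, adjusted p = 0.431), Isg15 (0.39 ± 0.31, adjusted p = 0.521) and Psmb9 (0.14 ± 0.18, adjusted p = 0.692) did not pass. Lgals3bp, 1 of the 2 higher members of the type I list, rose by 0.72 ± 0.11 (adjusted p = 0.0105). That call was lost without PBS replicate 2 or NTEV replicate 3 (adjusted p up to 0.0541). MHC class I genes had 3 of 23 members higher (7 adjusted over the list alone; median 0.27; camera adjusted p = 0.00327, but adjusted p = 0.180 with an estimated correlation). Without NTEV replicate 1, Tap1 (0.78 ± 0.21, adjusted p = 0.0749) was called at an adjusted p of 0.00773 and Cd40 (1.02 ± 0.26, adjusted p = 0.0603) at 0.0176.

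Glycolysis and hypoxia genes fell as a list here too, with 5 of 29 members lower and none higher (12 lower adjusted over the list alone; median -0.67; camera adjusted p = 4.27e-14, but adjusted p = 0.180 with an estimated correlation). Ankrd37, a hypoxia-induced ankyrin-repeat gene, fell by 3.41, and its call was lost without PBS replicate 2 or 3 (adjusted p up to 0.0650). Pdk1, the kinase that limits pyruvate entry into mitochondria, fell by 0.79 and lost its call without PBS replicate 2 or 3 or NTEV replicate 2 or 3 (adjusted p up to 0.0793). Further lists called by camera with the preset correlation, but not with an estimated one, were lysosome and phagosome (median 0.25, 1 of 33 members higher, adjusted p = 1.88e-04), p53 targets (0.41, 1 of 23, 6.23e-04), oxidative stress (0.25, 3 of 23, 0.00274), dendritic cell maturation (0.49, 1 of 14, 0.00444) and cell cycle (-0.23, 0 of 35, 6.23e-04). With an estimated correlation their adjusted p was 0.209, 0.288, 0.868, 0.288 and 0.910 in the same order. The oxidative stress list lost its call without PBS replicate 3 (adjusted p = 0.0567) or NTEV replicate 1 (adjusted p = 0.184), and the cell cycle list without NTEV replicate 2 (adjusted p = 0.191).

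In total 306 genes were called between NTEV and PBS by edgeR's quasi-likelihood test, 225 higher and 81 lower, with at least a 2-fold difference for 115 and 54 of them; DESeq2 called 584 higher and 242 lower, and edgeR called 19 when only the 6 libraries compared were fitted. This count rested heavily on single libraries: 113 without PBS replicate 1, 44 without PBS replicate 2, 34 without PBS replicate 3, 1685 without NTEV replicate 1, 69 without NTEV replicate 2 and 40 without NTEV replicate 3. In all 6 of those fits 28 genes were called, 15 higher and 13 lower.

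The comparison of ATEV with DNase-treated ATEV, at the same vesicle dose, asks what the DNase step removed. Many of the interferon-inducible genes that rose with ATEV were higher with intact than with DNase-treated vesicles. Gbp2 stood at 39.6 ± 8.02 against 2.62 ± 1.31 CPM (SD, n = 3; log2 difference 3.92 ± 0.34, adjusted p = 6.16e-05). The differences for Gbp7, Irgm2 and Irgm1 were 2.83, 2.56 and 1.70. Iigp1 (4 counts over the DNase-treated group), Tgtp2 (4 counts) and Serpina3f (4 counts) differed by 7.65, 7.93 and 6.20 on the log2 scale. In the interferon-gamma-inducible list 15 of 18 members were higher with ATEV (18 adjusted over the list alone; median 2.12; camera adjusted p = 2.65e-79, and adjusted p = 1.96e-05 with an estimated correlation), and 12 of these calls were kept whichever library was left out. Of the type I interferon-stimulated genes, 18 of 43 were higher (36 higher and 1 lower adjusted over the list alone; median 1.10; camera adjusted p = 4.86e-44, and adjusted p = 6.53e-04 with an estimated correlation). Zbp1 differed by 3.61, Irf7 by 1.67, Parp14 by 1.58 and Lgals3bp by 1.35, and these calls were kept in all 6 fits with 1 library left out.

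MHC class I genes were higher with intact ATEV in 17 of 23 cases (20 adjusted over the list alone; median 0.90; camera adjusted p = 2.63e-39, and adjusted p = 1.96e-05 with an estimated correlation). Psmb9 stood at 70.0 ± 13 against 16.8 ± 1.02 CPM (2.05 ± 0.19, adjusted p = 6.54e-05) and Tap1 at 144 ± 24.3 against 43.4 ± 7.87 CPM (1.73 ± 0.21, adjusted p = 0.00101). Nlrc5 differed by 0.90 and H2-Q7 by 3.39. H2-K1 differed by 0.65, with its call lost without DNase-treated ATEV replicate 2 (adjusted p = 0.0838). NF-kB targets and inflammatory cytokines had 5 of 26 members higher (10 adjusted over the list alone; median 0.58; camera adjusted p = 3.7e-10, and adjusted p = 7.24e-04 with an estimated correlation), with Il27 higher by 2.91. Dendritic cell maturation genes had 3 of 14 higher (6 adjusted over the list alone; median 0.64; camera adjusted p = 5.51e-06, and adjusted p = 0.0431 with an estimated correlation). Cd40 differed by 1.57, a call lost without DNase-treated ATEV replicate 2 (adjusted p = 0.0582). Fas was higher by 2.43, Lyz2 by 1.51 and the kinase Ikbke by 1.00. Lower genes were few: Cytip, a cytohesin-binding regulator of leukocyte adhesion, differed by -1.13 ± 0.19 (adjusted p = 0.00682) and the steroid reductase Srd5a1 by -1.07 ± 0.17 (adjusted p = 0.00525).

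Lists called by camera between intact and DNase-treated ATEV, but not with an estimated correlation, were macrophage markers (median 0.26, 1 of 14 members higher, adjusted p = 1.58e-04), oxidative stress (0.36, 1 of 23, 1.96e-04), glycolysis and hypoxia (-0.42, 0 of 29, 9.08e-07), cell cycle (-0.22, 0 of 35, 5.22e-04), p53 targets (0.11, 3 of 23, 0.00534), lysosome and phagosome (0.11, 2 of 33, 0.0107), DNA sensing (0.02, 4 of 27, 0.0331) and fibroblast markers (1.11, 0 of 8, 0.0304). With an estimated correlation the adjusted p was 0.208, 0.388, 0.272, 0.553, 0.272, 0.272, 0.208 and 0.459 in that order. The tested fibroblast markers lay near the floor, with a median of 0.628 CPM in PBS. Their median difference from the PBS mean was -1.42 in ATEV replicate 2 and 1.11 in ATEV replicate 3. Leaving out 1 library ended the call of the cell cycle list (ATEV replicate 1, adjusted p = 0.111; DNase-treated replicate 1, 0.339), p53 targets (ATEV replicate 1, 0.107; DNase-treated replicate 1, 0.0558), lysosome genes (ATEV replicate 2, 0.0683), DNA sensing (ATEV replicate 1, 0.0528; ATEV replicate 2, 0.0683; DNase-treated replicate 3, 0.161) and fibroblast markers (ATEV replicate 1, 0.166; ATEV replicate 3, 0.387; DNase-treated replicate 1, 0.176).

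The edgeR test called 194 genes between intact and DNase-treated ATEV, with 175 higher and 19 lower; DESeq2 called 346 higher and 133 lower. Without ATEV replicates 1, 2 and 3 in turn the count was 522, 104 and 103, and without DNase-treated replicates 1, 2 and 3 it was 145, 78 and 110. In all 6 fits 74 genes were called, 72 of them higher with intact ATEV.

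The comparison of ATEV with NTEV sets vesicles of activated against those of non-activated T cells, at unequal vesicle doses. Interferon-inducible genes were again among those that differed. Gbp2 stood at 39.6 ± 8.02 CPM with ATEV and 0.962 ± 0.321 with NTEV (SD, n = 3; log2 difference 5.34 ± 0.38, adjusted p = 5.14e-06). Iigp1, Tgtp2 and Serpina3f had 0 counts with NTEV and were at least 324-fold, 391-fold and 118-fold higher with ATEV, against a floor of 3 counts over the NTEV group. Zbp1 differed by 5.85, Gbp3 by 3.75, Irgm2 by 3.04, Oasl2, a 2'-5'-oligoadenylate synthetase-like protein, by 3.52, Lgals3bp by 1.46 and Ifi204 by 2.79. In the interferon-gamma-inducible list 14 of 18 members were higher with ATEV (16 adjusted over the list alone; median 2.59; camera adjusted p = 4.99e-114, and adjusted p = 4.3e-06 with an estimated correlation); placing Iigp1 at its bound leaves this median as it is. In the type I interferon-stimulated list 22 of 43 were higher (34 adjusted over the list alone; median 1.28; camera adjusted p = 8.4e-64, and adjusted p = 2.85e-04 with an estimated correlation).

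MHC class I genes were higher with ATEV than NTEV in 13 of 23 cases (20 adjusted over the list alone; median 0.91; camera adjusted p = 9.58e-39, and adjusted p = 1.57e-05 with an estimated correlation), including Psmb9 (2.11), Psme1 (1.11), Tapbpl (1.60), Tap1 (1.36) and Nlrc5 (0.91). NF-kB targets had 1 member higher and 1 lower (1 higher and 2 lower adjusted over the list alone; median -0.18; camera adjusted p = 0.15): Il27 was higher by 2.03, while Lcn2 stood at 3.19 ± 0.177 CPM with ATEV and 18.9 ± 6.74 with NTEV (-2.56 ± 0.35, adjusted p = 0.00204). The betaine and GABA transporter Slc6a12 (-1.14 ± 0.18, adjusted p = 0.00464) and the zinc transporter Slc39a4 (-1.44 ± 0.23, adjusted p = 0.00697) were also lower with ATEV. Complement C1qc was higher by 3.76, with its call lost without NTEV replicate 3 (adjusted p = 0.0770). The glycolysis and hypoxia list was not called between these groups (median -0.04, camera adjusted p = 0.911).

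Macrophage markers (median 0.46, 2 of 14 members higher, camera adjusted p = 3.16e-04), dendritic cell maturation (0.33, 1 of 14, 0.0101), cell cycle (-0.23, 0 of 35, 0.00188) and oxidative stress (-0.23, 0 of 23, 0.0101) were called with the preset correlation only, with adjusted p = 0.291, 0.291, 0.743 and 0.713 with an estimated correlation. The last 3 of these lists lost their calls without ATEV replicate 1 (adjusted p = 0.103, 0.258 and 0.422) and without NTEV replicate 1 (adjusted p = 0.172, 0.767 and 0.172), so that 4 lists rather than 7 were called without either library. Over all genes 124 were called by edgeR between ATEV and NTEV, 116 higher and 8 lower; DESeq2 called 254 higher and 107 lower. The count was 302, 95 and 82 without ATEV replicates 1, 2 and 3, and 111, 101 and 70 without NTEV replicates 1, 2 and 3. In all 6 fits 65 genes were called, 62 of them higher.

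**Figure D3:**
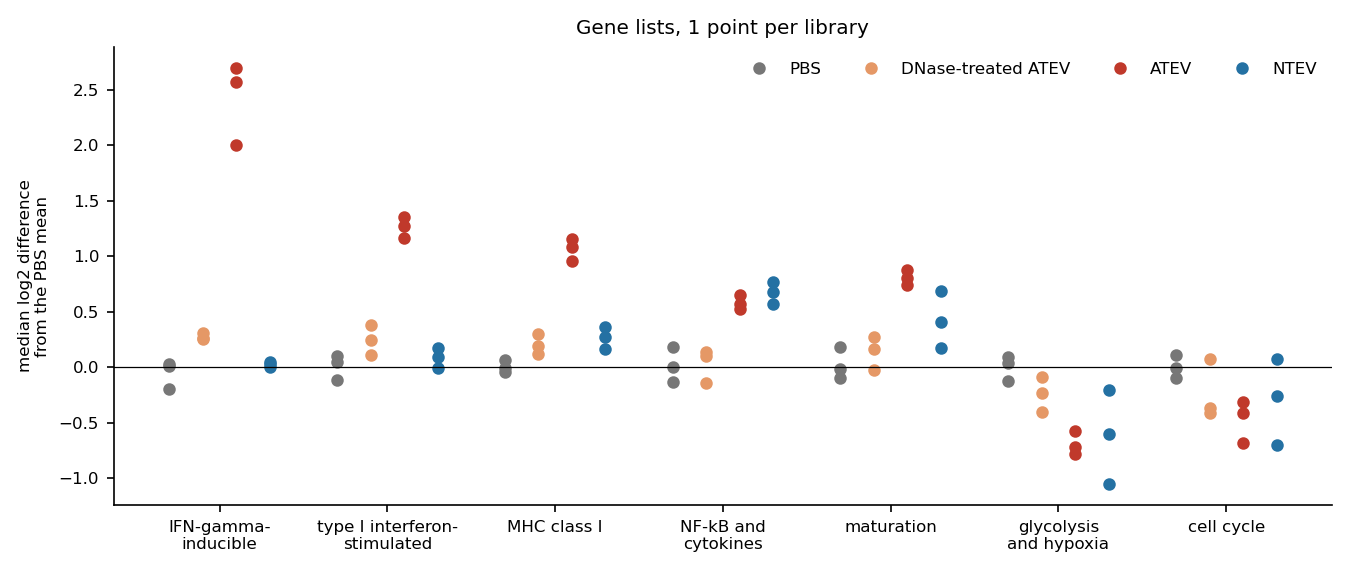
Median log2 difference from the PBS mean over the tested members of 7 gene lists (y axis), with 1 point per library coloured by group and the lists along the x axis. The 3 interferon and MHC class I lists stand highest in ATEV libraries, the NF-kB list is raised in ATEV and NTEV libraries, and the glycolysis list is lower in ATEV libraries (-0.578 and below) than in PBS libraries (-0.125 and above), while NTEV libraries range from -1.06 to -0.208.

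Calls of the comparisons were then set side by side. Of the 440 genes higher with ATEV than with PBS, 158 were also higher with ATEV than with DNase-treated ATEV, 100 were higher than with NTEV and 85 were higher than with both. Over these 440 genes the median log2 difference from PBS was 1.08 with ATEV, 0.55 with NTEV and 0.30 with DNase-treated ATEV, and 393 and 389 of them had a positive fold change with NTEV and DNase-treated ATEV; the genes were picked for a high value with ATEV, against the same PBS libraries. ATEV and NTEV shared 114 genes higher than PBS, where independent lists would share 7.47, and 38 lower, where they would share 1.15. Both lists were called against the same PBS libraries, so independence is not the value expected without change. Simulated unchanged groups against shared controls had 0 shared calls in each of 20 runs. Those groups were drawn from the same means, so few calls of any kind are expected there. This 0 is therefore no measure of how much the shared PBS libraries add to the overlap. Gbp7 was called in opposite directions. Without each library in turn the total of 152 shared calls became 61, 18 and 18 (PBS replicates 1, 2 and 3), 146, 48 and 95 (ATEV replicates 1, 2 and 3) and 644, 57 and 27 (NTEV replicates 1, 2 and 3).

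Across genes, which are not independent replicates, the fold changes of ATEV and NTEV against PBS correlated with r = 0.625, beside 0.499 in 20 simulations of unchanged groups against shared controls, and their covariance was 0.173 beside 0.0398, a difference of 0.133. For ATEV and DNase-treated ATEV r was 0.588 beside 0.5, and the covariance was 0.119 beside 0.0401, a difference of 0.0786. These 2 comparisons shared 0 calls in edgeR, since DNase-treated ATEV had none, and 26 in DESeq2; without DNase-treated ATEV replicate 1 they shared 7. The 3 PBS libraries cannot be split into groups of at least 2, so part of each excess may come from the shared controls.

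**Figure D4:**
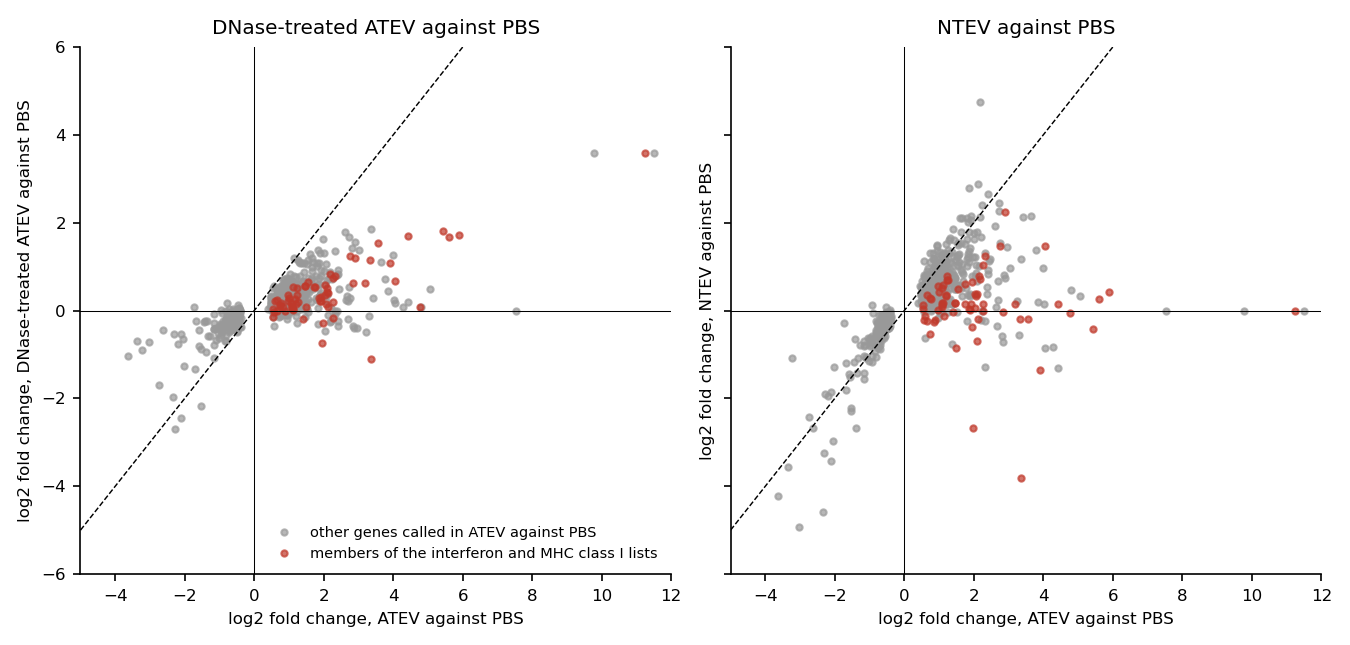
Log2 fold change against PBS after DNase-treated ATEV (left, y axis) and NTEV (right, y axis) for the 628 genes called between ATEV and PBS, plotted against their log2 fold change with ATEV (x axis); red points are members of the interferon and MHC class I lists, and the dashed line marks equal change. Most points lie nearer to 0 on the y axis than the dashed line, and the fold changes after DNase-treated ATEV span -2.70 to 3.59.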

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

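All tests of explanations in this part were chosen only after the result was seen. Gbp7 was singled out because groups differed in direction. It rose with ATEV (log2 fold change against PBS 3.91 ± 0.25, SE, adjusted p = 2.79e-06), fell with NTEV (-1.36 ± 0.29, adjusted p = 0.0287) and differed by 5.26 ± 0.28 between ATEV and NTEV (adjusted p = 4.33e-07). Its counts over 3 libraries were 123 in PBS, 1702 with ATEV, 52 with NTEV and 247 with DNase-treated ATEV. The fall with NTEV was called in the fit without NTEV replicate 1 but lost without each of PBS replicates 1, 2 and 3 and NTEV replicates 2 and 3 (adjusted p up to 0.121).

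Among 103 listed genes with too few counts to be tested, those were picked whose counts in each library of a treated group exceeded each PBS library, with at least 10 counts over the group; these differences were not tested. A gene without any change meets the ordering in about 5% of cases where counts are not tied, and 309 orderings were looked at. Ties at low counts and the minimum of 10 counts lower the share that meets the whole rule. By how much was not estimated, so 5% is not the number to set beside the genes found. With ATEV these were the class II transactivator Ciita (22 counts against 0 in PBS), Gbp4 (12 against 0) and the MHC class II chains H2-Aa (17 against 3), H2-Ab1 (28 against 1) and H2-Eb1 (19 against 6). With NTEV they were the actin-bundling gene Fscn1 (15 against 9) and the collagen cross-linking enzyme Lox (12 against 0), and with DNase-treated ATEV the class II chaperone subunit H2-DMb2 (30 against 7).

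The rise of interferon-inducible genes with ATEV was weighed against 3 technical explanations. RNA of the donor T cells carried over in the proportions of those cells was excluded as the source, since 27 of 33 T cell markers, picked for under 1 CPM in PBS alone, had a summed level of 0.825 CPM in PBS and 0.732 with ATEV, a change of -0.0191% of the rise of the interferon-gamma list; the other 6 had a median log2 fold change of 0.64 with ATEV, 0.53 with NTEV and 0.45 with DNase-treated ATEV, and selective loading of vesicles was not tested. Reads shared between near-identical gene copies were excluded as the whole of it, because 50 listed genes outside multi-copy families had a median log2 fold change of 1.11 and 36 of them rose. The DNase step acting other than by removing vesicle DNA remains open, as 0 groups received DNase without ATEV. Vesicle DNA sensed by the cells could account for the pattern, as could a vesicle component that the DNase treatment damaged or diluted, but NTEV, whose dose the labels equate with 5 µg/mL of vesicle DNA, had no called rise of the interferon-gamma list (median -0.01, camera adjusted p = 0.780).

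Lower glycolysis and hypoxia genes with ATEV and NTEV were weighed next. A culture state that differs between libraries, such as cell density, remains open: the gap between the lowest PBS library (-0.125) and the highest ATEV library (-0.578) was 0.453 on the log2 scale, less than the range of 0.848 within the NTEV group. TMM scaling was not the source: its factors averaged 0.978 in PBS, 1.01 in ATEV and 0.994 in NTEV, which differ too little to produce it. Under library size alone the higher of both list medians was -0.65, and with such factors that value could hardly have come out otherwise.

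The absence of calls between DNase-treated ATEV and PBS was the last pattern weighed. No value pointed to less power in that comparison, though it was not excluded: the biological coefficient of variation of its 6 libraries was 0.156 (0.128 to 0.175 with 1 library left out), beside 0.168 (0.144 to 0.188) for ATEV and PBS. These ranges overlap, while with PBS replicate 1, 2 or 3 left out of both comparisons it was lower each time (0.154, 0.175 and 0.153 beside 0.170, 0.188 and 0.169). The fit behind the 0 calls shares 1 estimate of the spread over all 12 libraries, so these separate values did not enter that test. A single library that stands apart remains open too. Leaving out 1 library gave at most 8 calls, but without DNase-treated ATEV replicate 1 the genes at an unadjusted p under 0.05 rose from 791 to 1766. This library lay at -30.4 on the first principal component, against 4.41 and 9.81 for the others of its group. It was not alone, as replicate 1 of PBS (-41.8) and of NTEV (-21.5) also lay lowest in their groups. ATEV replicate 1 (31.1) lay highest in its own. Departures from the group mean correlated between DNase-treated ATEV replicate 1 and replicate 1 of PBS (0.440) and NTEV (0.619). A state shared by these libraries was not tested.

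For each comparison the 6 libraries can be divided in 10 ways, too few for a share under 0.05. Every other division mixes libraries of both groups, so a real difference widens the spread and few calls are expected there. The counts of other divisions are therefore no measure of what chance gives. The real division gave 628 calls for ATEV against PBS (highest other 0), 0 for DNase-treated ATEV against PBS (highest other 0, so that 10 of 10 divisions had as many), 306 for NTEV against PBS (0), 194 for ATEV against DNase-treated ATEV (1) and 124 for ATEV against NTEV (0), and otherwise 1 of 10 divisions, the real one, had as many.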

How the results depend on the processing

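None of the 200 calls of named genes changed sign under any alternative. RLE size factors and DESeq2 kept all 200, no filter on low counts 197, the replicate block 193, library size alone 185, limma-voom 181 and the test against a minimum fold of 1.5 kept 87; at least 5 CPM in 3 libraries kept 159 of the 163 still tested, and only the 6 libraries compared kept 148 of 199. Counts under RLE, library size alone, limma-voom and the 5 CPM filter stayed within 1.5 times of the values reported, except where given below. No called gene list changed direction; with fry, 3 lists that were not called did (immediate early genes for ATEV against PBS, NF-kB targets for DNase-treated ATEV against PBS, glycolysis and hypoxia for ATEV against NTEV). The median log2 fold change over all genes stayed under 0.1 in size under every scaling.

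Genes called for ATEV against PBS numbered 1516 with DESeq2, 1317 with no filter on low counts, 1244 with only the 6 libraries compared, 1440 with the replicate block, 117 with the test against a minimum fold of 1.5, and 169 to 849 with 1 library left out. The share of higher genes fell from 70.1% to 55.9% with DESeq2, 55.6% with the block and 58.4% with only the 6 libraries. For DNase-treated ATEV against PBS there were 1 with library size alone, 37 with DESeq2, 47 with no filter, 1 with at least 5 CPM in 3 libraries, 1 with the replicate block and 0 to 8 with 1 library left out. NTEV against PBS gave 826 with DESeq2, 876 with no filter, 19 with only the 6 libraries compared, 27 with the minimum fold of 1.5 and 34 to 1685 with 1 library left out. ATEV against DNase-treated ATEV gave 479 with DESeq2, 394 with no filter, 66 with the minimum fold and 78 to 522 with 1 library left out; the share of higher genes was 72.2% in DESeq2 beside 90.2%. ATEV against NTEV gave 361 with DESeq2, 242 with no filter, 82 with only the 6 libraries compared, 57 with the minimum fold and 70 to 302 with 1 library left out; the share of higher genes was 70.4% in DESeq2 beside 93.5%. A minimum fold asks for more than a difference from 0 and so calls fewer genes; for the other alternatives the cause was not tested.

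Gene lists called with an estimated inter-gene correlation numbered 5 for ATEV against PBS, 0 for DNase-treated ATEV against PBS, 1 for NTEV against PBS, 5 for ATEV against DNase-treated ATEV and 3 for ATEV against NTEV. With fry they numbered 2 for DNase-treated ATEV against PBS, 4 for NTEV against PBS, 7 for ATEV against DNase-treated ATEV and 4 for ATEV against NTEV, where leaving out 1 library gave 4 to 9. Calls shared by ATEV and NTEV numbered 397 with DESeq2 and 18 to 644 with 1 library left out. Calls shared by ATEV and DNase-treated ATEV numbered 1 with library size alone, 26 with DESeq2, 1 with at least 5 CPM, 1 with the replicate block and 0 to 7 with 1 library left out; the cause was not tested.

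Only genes that were not called changed sign, and the cause was not tested. For DNase-treated ATEV against PBS, Cd40 was 0.0457 with library size alone and -0.232 to 0.0991 with 1 library left out; Tmem173 was 0.0598 with library size alone, 0.00660 with no filter, 0.000309 with only the 6 libraries compared and -0.0344 to 0.0155 with 1 library left out; Ccl5 ran from -0.431 to 0.244 and Psmb8 from -0.112 to 0.168. With 1 library left out, Ifit1 ran from -0.549 to 0.267 for NTEV against PBS. Cd86 ran from -0.0581 to 0.255 and Cgas from -0.122 to 0.211 for ATEV against DNase-treated ATEV, and Cd80 from -0.123 to 0.395 and Cxcl10 from -0.367 to 0.588 for ATEV against NTEV.

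Replicate numbers did not pair the libraries throughout. Of 18 same-number pairs, 6 had a correlation over 0.1 (-0.38 to 0.62) between their departures from the group mean. For 3 of 12 libraries the best correlation was with one of their own number. These were replicate 1 of PBS, NTEV and DNase-treated ATEV (PBS and NTEV 0.519, PBS and DNase-treated ATEV 0.440, NTEV and DNase-treated ATEV 0.619). ATEV replicate 1 correlated negatively with each of them (-0.158, -0.322 and -0.382). NTEV and DNase-treated ATEV also correlated for replicates 2 (0.346) and 3 (0.129). As a replicate block the numbers gave 1440 calls for ATEV against PBS (801 higher, 639 lower), 343 for NTEV against PBS, 261 for ATEV against DNase-treated ATEV and 135 for ATEV against NTEV, beside 628 (440 higher, 188 lower), 306, 194 and 124.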

Other observations

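The genes of these paragraphs, and the test that follows, were chosen only after their values were seen. Several genes outside the fixed lists changed with ATEV. Acod1, which makes the antimicrobial metabolite itaconate, increased from 58.6 ± 10.4 to 397 ± 90.0 CPM (SD, n = 3; log2 fold change 2.76 ± 0.33, SE, adjusted p = 3.66e-04) and stood at 71.2 ± 22 CPM after DNase-treated ATEV. With NTEV it stood at 170 ± 72.7 CPM (1.54 ± 0.31, adjusted p = 0.0255), a call lost without PBS replicate 1, 2 or 3 or NTEV replicate 3 (adjusted p up to 0.128), and ATEV and NTEV did not pass a test against each other (adjusted p = 0.104). The arginine-making enzyme Ass1 rose by 0.88 and complement C3 by 1.14. The interleukin-12 receptor subunit Il12rb1 rose from 1.62 ± 0.111 to 8.42 ± 1.10 CPM and lay at 2.12 ± 0.581 with NTEV and 1.61 ± 0.134 with DNase-treated ATEV. The surface receptors Slamf7 and Slamf8 rose by 3.64 and 3.85 and the receptor kinase Axl by 2.68. The collagenase Mmp8 fell by 2.02 and Cytip by 1.36. All of these ATEV calls were kept whichever library was left out. Ass1, C3, Slamf7, Mmp8 and Cytip were called in the same direction with NTEV (0.67, 1.32, 2.16, -1.30 and -1.43). Those NTEV calls were kept in every fit for C3 and Cytip, but were lost for Ass1 and Mmp8 without PBS replicate 2 or 3 or NTEV replicate 2 or 3 (adjusted p up to 0.0873 and 0.105), and for Slamf7 without any library but NTEV replicate 1 (adjusted p up to 0.0954).

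Further genes changed with NTEV, some of them with ATEV as well. Ebi3, a subunit of interleukin-27 and interleukin-35, rose from 7.16 ± 0.181 to 19.9 ± 4.55 CPM (1.47 ± 0.19, adjusted p = 0.00296), the protease Ctsk by 1.13, and the prostaglandin E synthase Ptges by 1.85. The immunoglobulin heavy chain Ighm dropped from 63.1 ± 21.3 to 13.8 ± 4.42 CPM, and Serpinf1 fell by 2.67. These calls were kept whichever library was left out. With ATEV, Ctsk (0.56, adjusted p = 0.0424), Ptges (1.41, 0.0125) and Serpinf1 (-1.38, 0.0424) were called in the same direction, and none of the 3 was called between ATEV and NTEV. These ATEV calls were lost for Ctsk without PBS replicate 2 or 3 or ATEV replicate 2 or 3 (adjusted p up to 0.2), for Ptges without PBS replicate 3 or ATEV replicate 2 (up to 0.0679) and for Serpinf1 without any library but ATEV replicate 1 (up to 0.163). Arg1, an arginine-degrading enzyme, fell by 3.37, a call that held only without NTEV replicate 1 and was lost without PBS replicate 1, 2 or 3 or NTEV replicate 2 or 3 (adjusted p up to 0.186).

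With DNase-treated ATEV, Lgals3bp (0.83 ± 0.11), Cd24a (-1.70 ± 0.26) and the integrin Itgal (1.15 ± 0.17) were among the genes with the smallest adjusted p of that comparison, 0.0612 each, and did not pass. Without DNase-treated ATEV replicate 1 they were called, at an adjusted p of 0.0479, 0.0496 and 0.00145, and Cd24a was also called without PBS replicate 1 (0.0458).

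A hypothesis was that a type I interferon made by the DC2.4 cells drives the rise of interferon-inducible genes. The 18 type I interferon genes together had 0 counts in the ATEV libraries, 2 in PBS, 1 with NTEV and 0 with DNase-treated ATEV, and Ifng had 0 in all groups. This leaves the hypothesis open, because an interferon pulse that ended before the harvest could leave 0 such transcripts. These RNA counts also do not bear on interferon protein added with the vesicles, which was not measured here.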
